A study of Mus musculus with 9 samples.

How the data were processed

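Single cells were profiled from the testes of untreated mice of 9 ages, with 1 mouse per age, as the labels state. Per the labels' protocols, testis tissue was digested with collagenases, neutral protease and DNase at 37°C for 40 min, strained, depleted of dead cells on magnetic columns, and taken into droplet-based 3' libraries that were sequenced on an Illumina instrument. Cell Ranger 3.1.0 and the mm10 build are named in the submitters' processing notes. The authors deposited a table of raw UMI counts (unique molecular identifiers, whole numbers, no normalization) for each age, with 27998 genes by symbol in rows and barcodes in columns. No cell annotation was used here.

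The deposited tables had already been filtered. The lowest number of detected genes per barcode was 501 or 502 in the tables of 3, 6, 8, 11 and 14 days, 721 at 17 days, 1804 at 21 days, 1805 at 25 days and 1423 at 35 days, and the highest mitochondrial share was just under 10% in each. This gene minimum moved with age, so a share of cells can be set by it. Depth ranged from 54607510 UMIs (17 days) to 99867357 UMIs (25 days) per table, with medians of 6303 to 10806 UMIs per barcode. The tables of 3 and 11 days were identical in all values and in all 6190 barcodes, suffix included, while no other pair of tables shared a full barcode. They were counted as 1 library of unknown age and left out of every test across ages, a rule fixed before the data were examined. That left 7 mice of known age.

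Cells with at least 500 genes and at most 20% mitochondrial UMIs were kept, which removed no barcode. Scrublet in scanpy 1.11.5 marked 237 cells of the duplicated library, 432 at 6 days, 161 at 8 days, 107 at 14 days, 23 at 17 days, 0 at 21 days, 0 at 25 days and 1 at 35 days. At 17, 21, 25 and 35 days this is under 0.5%, a rate at which the caller was taken not to have worked, so doublets can remain in those libraries. The cause of the low rate was not tested. After removal of the marked cells, 58481 of 59442 cells remained. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were taken outside chromosomes X, Y and the mitochondrial genome, and 30 principal components with 15 neighbours gave 39 Leiden clusters at resolution 1. No integration of libraries was applied, and several clusters held cells of a single library.

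Clusters were named "X-like" from marker genes fixed before the data were examined. The scoring rule was not fixed then. It was written after the clusters had been seen, several ways of scoring were looked at, and the rule was changed after the names from its earlier version had been seen, because that version left clusters 0, 17 and 22 unnamed. The earlier version is kept as an alternative. In the rule used, a cluster was scored by the mean relative level and by the mean z-score of each marker set. Close calls were settled by markers, and by the members of the mature Sertoli and acrosome lists, among the 10 genes with the highest fold over the other clusters. A name needed at least 3 markers at 10 CPM or more. Clusters of mostly predicted doublets, with leading genes of another class, or with low UMIs and no own marker among the leading genes stayed unnamed. Undifferentiated and differentiating spermatogonia could not be named apart reliably and were merged. The number of protamine and transition protein UMIs per cell in each cluster was counted only after the names had been given, and no name was changed by it. Names were rebuilt here and may differ from those of the study.

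Gene symbols were placed on chromosomes with GENCODE M21 on mm10, which matched 26711 symbols. RefSeq symbols and synonyms matched 618 more, and 669 stayed unmatched. Coordinates are from GENCODE on mm10.

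Shares of kept cells were given with exact 95% binomial intervals and summed CPM values with exact Poisson intervals, both covering counting error only. Where a class had 0 cells, the limit given is 3 cells of the total. Pearson's r and Spearman's rho of each share with log2 of the age were tested with exact two-sided permutation tests over 7 mice, adjusted by Benjamini-Hochberg over 8 classes. These 8 were chosen after the data had been seen. Sertoli-like cells were left out because late Sertoli-type clusters stayed unnamed, and meiotic and later germ classes because they were absent at the young ages or split between clusters by age. For trends in expression, UMI counts were summed per mouse and class and tested against log2 of the age with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr, Benjamini-Hochberg at 0.05). Genes over 5 times higher in another class of at least 200 cells were removed, since free RNA of other cells can reach the droplets. The fixed setting asked for at least 6 mice with 50 cells of the class. Only stromal-like cells met it. For peritubular myoid-like, Leydig-like, endothelial-like and macrophage-like cells a minimum of 20 cells, also fixed before the data were examined, gave 6 mice and is reported instead. Sertoli-like cells and undifferentiated spermatogonia had too few mice, so no trend was tested in them and none of the other settings fixed for those trends was run. Gene lists fixed before the data were examined were tested with camera in limma 3.58.1 (preset correlation 0.01, two-sided) over 17 pairs of list and class. Naming markers were left out of the lists, and only members that passed the filters on low counts and on genes of other classes were tested.

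The X-linked share of nuclear UMIs was compared within mice between late-spermatocyte-like and spermatogonia-like cells with an exact two-sided sign-flip test. The merged spermatogonia took the place of the undifferentiated class that had been planned. Where no test was possible, a list's median log2 ratio between 2 libraries was set against 10000 random lists of the same size matched on mean expression, as a description of those libraries. Genes named in the text follow a rule fixed before the data were examined: per class the 10 rising and 10 falling genes with the largest slopes among those called with a mean of at least 50 CPM, leaving out naming markers, mitochondrial, ribosomal protein and Gm- or Rik-named genes, and up to 4 called members of each list, or up to 2 by mean CPM if none was called. The text gives part of these. Genes called in all 5 classes, and genes that define clusters, are named outside the rule.

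Alternatives covered DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, age in days, all genes kept or a limit of 2 times for genes of other classes, a stricter cell filter of 1000 genes and 10% mitochondrial UMIs, doublets kept, Leiden resolution 2, each mouse left out, the duplicated library counted at 3 or at 11 days, and estimated correlation in camera. Chosen after seeing the data were at least 1800 genes in every library, removal of the top 5% of doublet scores, cluster 15 counted as stromal-like, the earlier naming rule, clusters 8 and 21 counted as Sertoli-like, and the lists with the duplicated library at 3 or at 11 days. So were clusters 8, 15, 21 and 36 added to the somatic denominator, cluster 2 counted as early spermatocyte, cluster 18 counted as stromal-like, and the gene lists and the values of cluster 1 at resolution 2. The trend test was checked on simulated counts with about 100 changed genes per class at each of 2 slopes. At a slope of 1 it recovered 99% of changed genes in stromal-like cells, 95% in peritubular myoid-like, 92% in Leydig-like, 71.7% in endothelial-like and 20% in macrophage-like cells. At a slope of 0.5 it recovered 36%, 31%, 13%, 14.1% and 1.01% in the same order. False calls made up 4.49% to 11.0% of calls. Python 3.11.15 and R 4.3.3 were used.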

Results

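Single-cell expression was measured in the testes of mice from 3 to 35 days of age, a period that runs from the first spermatogonia to the first wave of spermatids. The 9 deposited tables held 5485 to 9997 barcodes each. The tables of 3 and 11 days were identical and were counted as 1 library, with 6190 barcodes and 79354158 UMIs, whose age is not known. The other tables held 98932665 UMIs at 6 days, 56056215 at 8 days, 65741626 at 14 days, 54607510 at 17 days, 88964531 at 21 days, 99867357 at 25 days and 97508630 at 35 days. Each age is 1 mouse without replicates, so no age was tested against another, and tests concern trends over the mice of known age. For trends of shares and of single genes, p-values therefore measure the scatter of single mice around a line. The p-values of gene lists by limma camera instead compare the members of a list with the other genes. They depend on the correlation assumed between members and are not a measure of scatter between mice alone.

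Germ cells went from a small minority to nearly all kept cells. They made up 9.50% of cells at 6 days (95% exact binomial interval 8.92 to 10.1) and 9.22% at 8 days, then 46.5% at 14 days, 55.6% at 17 days, 92.0% at 21 days, 87.6% at 25 days and 94.3% at 35 days. Early-spermatocyte-like cells, led by the synaptonemal complex genes Sycp3 and Sycp1, were 0 of 9565 cells at 6 days, which allows a share of up to 0.0314%. At 8 days they were 0 of 5903 cells, with a limit of 0.0508%. They made up 2.39% at 14 days and 5.73% at 17 days. Cluster 2, named spermatogonia-like by its leading genes Stra8 and Rhox13, scored first as early spermatocyte and also expressed Dmc1. Counted as early spermatocytes, it raises these shares to 15.6% and 13.5%. Later, early-spermatocyte-like cells were 44 of 9336 cells at 21 days, 94 of 9912 at 25 days and 16 of 6858 at 35 days. Late-spermatocyte-like cells were 6.15% of cells at 14 days, 25.1% at 17 days and 37.4% at 21 days. Round-spermatid-like cells were 1 of 5462 cells at 17 days, 20.1% at 21 days, 10.4% at 25 days and 42.5% at 35 days. Elongating-spermatid-like cells of cluster 33, led by the protamine genes Prm1 and Prm2, which package sperm DNA, were 2.74% at 21 days, 15.96% at 25 days and 5.15% at 35 days. Cluster 35 was given the same name, and with it the shares were 4.36%, 41.3% and 5.53%. Its 2508 cells at 25 days had a median of 4145.5 UMIs and scored first as late spermatocyte by relative level. They held 40.18 UMIs of protamine and transition protein transcripts per cell, against 349.1 in cluster 33 and 32.89 to 49.46 in the classes of at least 40 cells other than spermatids. At 25 days these transcripts therefore do not support the name of cluster 35. Its 151 cells at 21 days held 20.45 per cell, against 3.746 to 5.35 in those classes of at least 30 cells. Its 26 cells at 35 days held 34.42, against 3.628 in stromal-like and 6.70 in late-spermatocyte-like cells. At these 2 ages the values go with spermatids. Round-spermatid-like cells held 19.39 and 19.42 per cell there, and cluster 33 held 360 and 468.7. The values thus do not support elongating over round spermatids. Late-spermatocyte-like cells were 4.02% at 25 days and 1195 of 6858 cells at 35 days. Late germ cells that could not be resolved were 25.3% of cells at 25 days and 23.2% at 35 days. Late-spermatocyte-like cells lay in cluster 9 at 14 and 17 days (medians of 1450 and 2153.5 UMIs) and in clusters 10, 27 and 29 later. The gene minimum of the tables of 21 and 25 days is over 1800 per barcode against 501 or 502 in the young tables, which can set these shares. The shares also depend on the clustering. At Leiden resolution 2 late-spermatocyte-like cells were 3.46% at 14 days, 16.2% at 17 days and 13.3% at 21 days, and elongating-spermatid-like cells 17.98% at 25 days. Unresolved late germ cells were then 53.3% at 21 days and 51.8% at 25 days. An early-spermatocyte-like cluster (34) of that resolution held 143 cells at 21 days, 112 at 25 days and 143 at 35 days. These are more than the 44, 94 and 16 cells given above, so the low late counts of this class depend on the clustering. A spermatogonial cluster led in part by haemoglobin genes stayed unnamed there, which left spermatogonia-like cells at 4.50% at 6 days and 0.712% at 8 days.

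**Figure D1:**
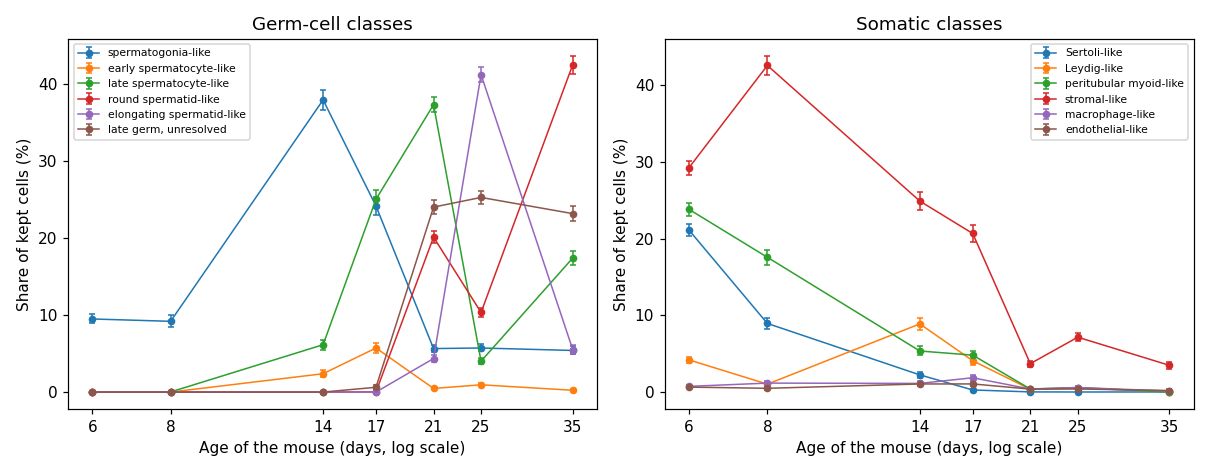
Share of kept cells (%) in each named class against the age of the mouse (days, log scale), germ-cell classes on the left and somatic classes on the right, 1 mouse per age; points are shares and bars are exact 95% binomial intervals. Spermatogonia-like cells reach 38.0% at 14 days, round-spermatid-like cells 42.5% at 35 days, and stromal-like cells go from 42.6% at 8 days to 3.48% at 35 days. Elongating-spermatid-like cells include cluster 35, whose protamine and transition protein transcripts are at the level of other classes at 25 days.

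Among somatic cells, peritubular myoid-like cells, the contractile layer around the tubules, went from 23.8% of kept cells at 6 days to 17.6% at 8 days, 5.35% at 14 days, 4.82% at 17 days and 0.396% at 21 days, with 0 of 6858 cells at 35 days, which allows up to 0.0437%. Their share fell with age over 7 mice (r = -0.95, exact permutation p = 0.000397, adjusted over 8 classes 0.00318; rho = -0.96, exact permutation p = 0.00278, adjusted 0.0222). Stromal-like cells were 29.3% at 6 days, 42.6% at 8 days, 20.7% at 17 days and 3.71% at 21 days. From 21 days they lay almost all in cluster 31, a close call that scored first as mesothelial by z-score. They fell as a share of all cells (r = -0.88, exact permutation p = 0.00952, adjusted 0.0381; rho = -0.93, exact permutation p = 0.00675, adjusted 0.0270). T- or NK-like cells, from 1.08% at 8 days to 0.0214% at 21 days, fell by r (-0.86, exact permutation p = 0.0175, adjusted 0.0466) but not by rho (-0.79, exact permutation p = 0.0480, adjusted 0.0960). Without the mice of 6 and 8 days, the farthest from the median age, r was -0.87, -0.86 and -0.61 for these classes. Within the 4 mice of low gene minimum rho was -1 for myoid-like, -0.8 for stromal-like and -0.6 for T- or NK-like cells, and within the 3 mice of high gene minimum -0.5, -0.5 and 1, without a test. With at least 1800 genes in every library, so at the same minimum, the fall of myoid-like cells was still called (r = -0.96, exact permutation, adjusted p = 0.00794). It rests on the name of cluster 18, which held 992 of the 1037 myoid-like cells at 8 days. That cluster scored first as stromal by relative level, had both Tcf21 and Tagln among its leading genes, and was a close call. Counted as stromal-like, it leaves 0.762% myoid-like cells at 8 days and ends the calls for myoid-like (r = -0.71, exact permutation, adjusted p = 0.111), stromal-like (r = -0.81, exact permutation, adjusted p = 0.0992) and T- or NK-like cells (r = -0.86, exact permutation, adjusted p = 0.0992). The share of T- or NK-like cells does not involve cluster 18, and for them only the adjustment over the classes changed.

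The fall of stromal-like cells held only against all kept cells, as germ cells filled the late libraries. Among named somatic cells alone their share rose (r = 0.93, exact permutation, adjusted p = 0.00529). So did those of endothelial-like (r = 0.83, exact permutation, adjusted p = 0.0378) and vascular mural-like cells (r = 0.84, exact permutation, adjusted p = 0.0345). Myoid-like cells fell there too (r = -0.99, exact permutation, adjusted p = 0.00238). These shares leave out the unnamed clusters 8, 15, 21 and 36. With those counted as somatic, stromal-like cells were 47.0% of somatic cells at 17 days instead of 61.0%. In that count r was 0.88 for stromal-like (exact permutation, adjusted p = 0.0325), 0.86 for endothelial-like (exact permutation, adjusted p = 0.0325), 0.83 for vascular mural-like (exact permutation, adjusted p = 0.0384) and -0.98 for myoid-like cells (exact permutation, adjusted p = 0.00238). Spermatogonia-like cells fell as a share of germ cells (r = -0.93, exact permutation, adjusted p = 0.00238) but not of all cells (r = -0.16, exact permutation p = 0.766, adjusted 0.766; rho = -0.68, exact permutation p = 0.110, adjusted 0.139). Leydig-like (r = -0.39), endothelial-like (r = -0.36), vascular mural-like (r = -0.65) and macrophage-like cells (r = -0.41) passed no test against all cells. At that gene minimum of 1800 the call was lost for stromal-like cells (r = -0.84, exact permutation, adjusted p = 0.0770) and for T- or NK-like cells (r = -0.77, exact permutation, adjusted p = 0.0868). The earlier naming rule, which left clusters 17 and 22 unnamed, gave r = -0.36 for stromal-like and -0.47 for myoid-like cells, with no call. Leaving out the mouse of 14, 17, 21, 25 or 35 days ended the stromal call (r = -0.88, -0.89, -0.90, -0.86 and -0.85), and leaving out any of the 7 mice ended the call for T- or NK-like cells (r from -0.91 to -0.84). Counting the duplicated library at 3 days ended the calls for myoid-like (r = -0.78), stromal-like (r = -0.75) and T- or NK-like cells (r = -0.59), and age in days ended them too (r = -0.85, -0.87 and -0.77). Counting that library at 11 days kept all 3 calls (r = -0.96, -0.88 and -0.84, exact permutation, adjusted p = 0.000397, 0.0156 and 0.0156).

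Transcripts of the X chromosome, which is silenced during meiosis, were scarce in late spermatocytes. X-linked genes gave 1.91% ± 0.211 (SD, n = 5 mice of 14 to 35 days) of nuclear UMIs in spermatogonia-like cells. In late-spermatocyte-like cells they gave 0.269% ± 0.0701. Clusters within that class differed: at 21, 25 and 35 days X-linked shares were 0.123%, 0.171% and 0.111% in cluster 10, which is rich in UMIs, and 0.658%, 0.745% and 0.685% in cluster 29, which held 2551 of 3488 such cells at 21 days. The share was lower in 5 of 5 mice, with a mean difference of -1.64 percentage points (exact sign-flip p = 0.0625, two-sided, the smallest this design can give). On the log2 scale X changed by -2.86 between the classes, against -0.23 for chromosome 7, the next lowest, and 0.27 for chromosome 12, the highest. Round-spermatid-like cells had X-linked shares of 1.28%, 2.02% and 1.08% at 21, 25 and 35 days. Genes of X were kept out of the clustering, and the 2 classes lie in different clusters before and after 21 days (spermatogonia-like in clusters 0, 1 and 2, then 32).

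**Figure D2:**
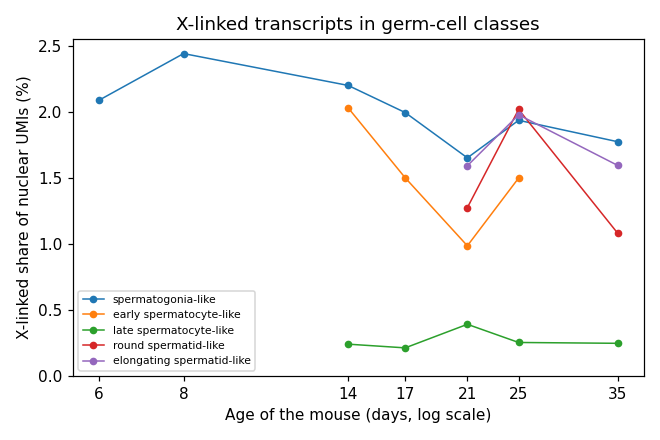
X-linked share of nuclear UMIs (%) in 5 germ-cell classes against the age of the mouse (days, log scale); each point is the summed UMIs of at least 20 cells of 1 mouse. Late-spermatocyte-like cells lie between 0.213% and 0.391%, below every other class at each age.

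Gene lists for stages of spermatogenesis, fixed beforehand, are given for the whole libraries without a test. Meiotic chromosome genes summed to 203 CPM at 6 days, 1828 CPM at 14 days and 2285 CPM at 17 days. Acrosome genes, which build the cap of the sperm head, went from 7.73 CPM at 6 days to 312 CPM at 14 days, 1608 CPM at 17 days and 8068 CPM at 21 days. Sperm flagellum genes went from 58.1 to 732, 2899 and 11845 CPM at these ages, and the list named testis-specific energy metabolism from 858 to 1761, 5631 and 14593 CPM. That list also holds general glycolysis genes, so its level at 6 days cannot be read as testis-specific expression. Spermatid chromatin genes were at 65.7 CPM at 6 days and 203 CPM at 17 days, and reached 2492 CPM at 21 days and 4205 CPM at 25 days.

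Sertoli-like cells, the nurse cells of the tubule, were numerous enough only at 6 days (2019 cells, cluster 23), 8 days (528 cells, cluster 24) and 14 days (123 cells, cluster 6), so 14 days is set against 6 days without a test. All 16 measured members of the mature Sertoli list were higher at 14 days, with a median log2 ratio of 1.82 (percentile 100 among random lists). Clu, an extracellular chaperone, went from 2383 to 4459 CPM. This list had also been used to settle close names. Cluster 6 was such a name, with the members Defb36 and Wfdc10 among its leading genes, so the percentile is not independent of the naming. Of the blood-testis barrier list 9 of 12 members were higher (median 0.72, percentile 99.5). Its tight junction gene Cldn11 went from 184 CPM (exact Poisson interval 179 to 189) to 1288 CPM (1236 to 1342), while Gja1, a gap junction gene, went from 454 to 209 CPM. Of the immature Sertoli list 9 of 11 members were lower (median -0.97, percentile 0.01), and of the proliferation list 37 of 39 (median -1.29, percentile 0), with the mitotic gene Ube2c at 307 and then 13.1 CPM. Cholesterol biosynthesis genes (median 0.18, percentile 39.1) and imprinted growth genes (median 0.23, percentile 57.7) lay inside the range of random lists. With the unnamed Sertoli-type clusters 8 and 21 added, the barrier list was at percentile 93 and the cholesterol list at 78.1.

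In stromal-like cells, imprinted genes that control fetal growth fell together with age. Of 15 measured members 14 fell (14 adjusted over the list alone) and none rose, with an adjusted p of 4.14e-08 by limma camera over 17 tests (adjusted p = 0.0655 with an estimated correlation). H19, a maternally expressed long noncoding RNA (chromosome 7, 142575529 to 142578143), was at 530.5 CPM at 6 days, 21.3 CPM at 14 days and 0 CPM at 35 days. Its slope was -4.91 ± 0.45 log2 units per doubling of age (SE, 7 mice). Dlk1, an inhibitor of adipocyte differentiation (chromosome 12, 109452823 to 109463336), went from 6093 to 1527 and 61.5 CPM (slope -2.93 ± 0.24). Mest and Peg3 fell with slopes of -2.18 ± 0.18 and -1.90 ± 0.20. The angiotensin receptor gene Agtr2 (-5.57 ± 0.53) and the growth factor genes Ptn (-2.18 ± 0.21) and Mdk (-1.86 ± 0.15) fell as well. Gsn, which severs actin filaments, rose from 328.6 CPM at 6 days to 10018 CPM at 35 days (slope 2.18 ± 0.34), with Ecm1 (2.09 ± 0.18), Pi16 (2.06 ± 0.29) and the chemokine gene Cxcl14 (1.83 ± 0.20). Of the fibrillar matrix list 9 of 17 members fell and none rose (9 adjusted over the list alone), Fn1 (-1.37 ± 0.32) and Fbn2 (-1.70 ± 0.14) among them, with an adjusted p of 0.00136 by limma camera (adjusted p = 0.252 with an estimated correlation). The proliferation list was not called (limma camera, adjusted p = 0.247, 1 of 6 members rising and 3 falling, the same adjusted over the list alone). Only these 6 of its 40 genes passed the filters on low counts and on genes of other classes, so most of the list was not tested. With all genes kept its direction reversed, without a call. Cycling cells of cluster 15, led by Mki67 and Tk1, stayed unnamed and made up 5.51% of cells at 6 days, 3.69% at 8 days and 0.437% at 14 days.

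In all, 1534 genes rose and 1782 fell with age in stromal-like cells, of 9041 tested (edgeR quasi-likelihood test over 7 mice, Benjamini-Hochberg). Most of these cells lay in cluster 17 at 6 days, 4 at 8 days, 14 at 14 and 17 days and 31 from 21 days. The name of cluster 31, on which the late values rest, was a close call. It scored first as stromal and second as late spermatocyte by relative level, and first as mesothelial by z-score. Its leading genes, with the stromal marker Dcn among them, settled the name. Without the mouse of 6 days 2142 genes were called and without that of 8 days 2037. Counting the duplicated library at 3 days gave 1118 genes, without Gsn and Pi16, and at 11 days 3583. The earlier naming rule gave 2148 over 6 mice. The counts depend on the filter against genes of other classes: with all genes kept 4511 rose and 3036 fell, and with a limit of 2 times 1335 genes were called.

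**Figure D3:**
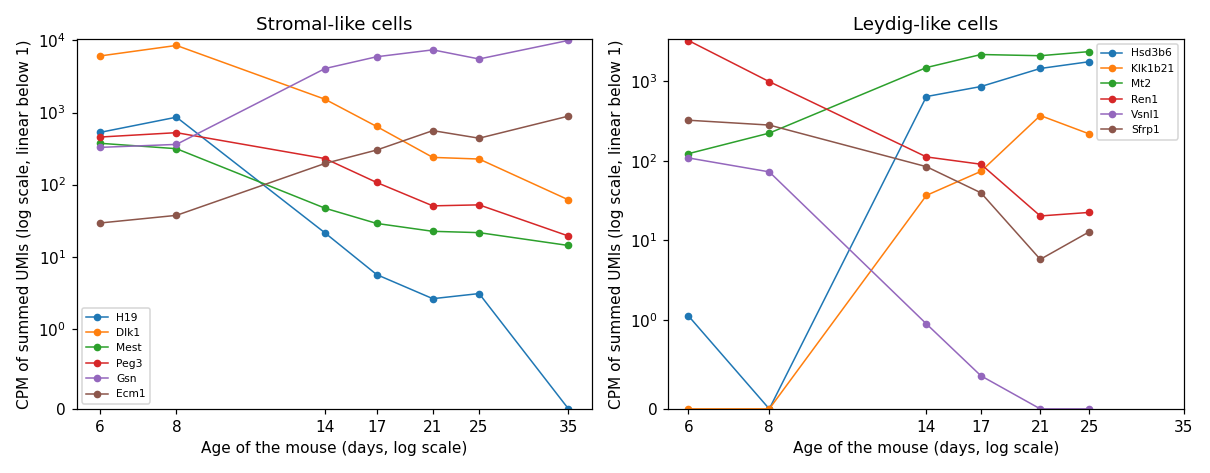
CPM of summed UMIs (log scale, linear below 1) against the age of the mouse (days, log scale) for 6 genes in stromal-like cells on the left and 6 genes in Leydig-like cells on the right, each point 1 mouse. H19 goes from 530.5 CPM at 6 days to 0 CPM at 35 days in stromal-like cells, and Hsd3b6 from 1.13 CPM at 6 days to 1742 CPM at 25 days in Leydig-like cells.

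Contractile genes rose with age in peritubular myoid-like cells, which lay in different clusters at different ages. Of the smooth muscle contraction list 11 of 18 members rose and none fell (15 adjusted over the list alone), with an adjusted p of 2.53e-06 by limma camera (adjusted p = 0.194 with an estimated correlation). Lmod1, which nucleates actin filaments, rose by 1.15 ± 0.21 log2 units per doubling of age (SE, 6 mice), Tpm2, a tropomyosin gene, by 1.00 ± 0.17, and the intermediate filament gene Synm by 3.32 ± 0.31. Of the imprinted growth genes 8 of 11 fell (9 adjusted over the list alone), with H19 at -4.01 ± 0.46 and Igf2, a fetal growth factor, at -1.91 ± 0.26 (limma camera, adjusted p = 5.58e-06, and 0.0844 with an estimated correlation). Igfbp5, which binds insulin-like growth factors (chromosome 1, 72857932 to 72874884), went from 480.9 CPM at 6 days to 0.744 CPM at 14 days. The proliferation list fell, 5 of 8 members (5 adjusted over the list alone, limma camera, adjusted p = 0.00707, and adjusted p = 0.0732 with an estimated correlation), including the replication genes Mcm4 (-1.36 ± 0.22) and Mcm6 (-1.29 ± 0.16). Most genes of this list did not pass the filters, and with all genes kept the list was not called. The fibrillar matrix list, with 1 member rising and 7 falling of 18 (2 and 7 adjusted over the list alone), was not called (limma camera, adjusted p = 0.0711), but it was without the mouse of 6 days (adjusted p = 0.00385). In all, 939 genes rose and 1026 fell of 8241 tested over 6 mice by edgeR (4134 called with all genes kept, 1042 with a limit of 2 times), with most cells in cluster 22 at 6 days, 18 at 8 days and 16 later. Cluster 22 was a close call too. The earlier naming rule left it unnamed, with under 3 detected markers, and then 5 mice remained and no trend was tested. A change of cell population was not told apart from age. With the close call of cluster 18 counted as stromal-like 1992 genes were called, and the contraction list still was (limma camera, adjusted p = 2.35e-06). With the duplicated library counted at 3 days 1 gene was called, and the proliferation list was not (limma camera, adjusted p = 0.354). Counting it at 11 days gave 2021 genes.

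Adult Leydig genes rose with age in Leydig-like cells, the source of testosterone, while the fetal list was not called. These cells formed a single cluster (13), but Leiden resolution 2 split them into cluster 19, led by Cyp17a1 and Ren1, and cluster 18, led by Hsd3b6 and Aldh1a1. Cluster 19 held 270 cells at 6 days, 19 at 8 days and 0 from 14 days on, and cluster 18 held 13, 39 and, at 14 days, 486 cells. The values below therefore include a change in the mixture of these cells. Of the adult Leydig list 7 of 10 members rose and none fell (8 adjusted over the list alone), with an adjusted p of 2.53e-06 by limma camera (adjusted p = 0.0480 with an estimated correlation). Hsd3b6, a steroid dehydrogenase of adult Leydig cells (chromosome 3, 98805504 to 98814443), was at 1.13 CPM at 6 days, 637 CPM at 14 days and 1742 CPM at 25 days (slope 5.12 ± 0.72, SE, 6 mice). The kallikrein genes Klk1b21 (4.86 ± 0.47), Klk1b24 (4.81 ± 0.48) and Klk1b27 (5.16 ± 0.62) rose too, but belong to a family of near-identical copies that can share reads. Ren1, the renin gene (chromosome 1, 133350510 to 133360325), fell from 3208 CPM at 6 days to 22.5 CPM at 25 days (-3.57 ± 0.17), and the calcium sensor gene Vsnl1 fell with a slope of -5.26 ± 0.45. Among the rising members of the fetal Leydig list was Vcam1 (slopes of 0.919 to 1.21 with a mouse left out), a leading gene of cluster 18 at resolution 2. The fetal list, 2 members rising and 3 falling of 6 (the same adjusted over the list alone), was not called (limma camera, adjusted p = 0.128). It was called without the mouse of 21 days (adjusted p = 0.0417), and turned upward without that of 6 or 8 days (adjusted p = 0.946 and 0.995).

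Imprinted growth genes fell in Leydig-like cells as well, 6 of 9 members (6 adjusted over the list alone, limma camera, adjusted p = 2.94e-06, and adjusted p = 0.0307 with an estimated correlation), including Peg3 (-1.62 ± 0.21) and the cell-cycle inhibitor gene Cdkn1c (-1.86 ± 0.16). The proliferation list fell, 5 of the 9 members that passed the filters (7 adjusted over the list alone, limma camera, adjusted p = 0.00136, and adjusted p = 0.0855 with an estimated correlation). It was not called without the mouse of 6 days (adjusted p = 0.0597) or with the duplicated library counted at 3 days (adjusted p = 0.132). Cholesterol biosynthesis, which feeds steroid synthesis, was not called (limma camera, adjusted p = 0.0711, 3 of 23 members rising, 3 adjusted over the list alone). Without the mouse of 6, 17 or 21 days it was called (adjusted p = 2.39e-06, 0.0316 and 0.0249), and without that of 25 days it turned downward (adjusted p = 0.548). In all, 663 genes rose and 696 fell of 7670 tested over 6 mice by edgeR (2830 called with all genes kept, 649 with a limit of 2 times). Leaving out the mouse of 6, 8 or 17 days gave 440, 905 and 877 genes, and counting the duplicated library at 3 days gave 0 by edgeR (1057 genes at an unadjusted p under 0.05). Counting it at 11 days gave 1594.

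Endothelial-like cells lost imprinted growth genes too, 4 of 8 members (5 adjusted over the list alone, limma camera, adjusted p = 0.000445, and adjusted p = 0.0460 with an estimated correlation), with Mest at -3.43 ± 0.27 and Grb10, an adaptor of growth factor receptors, at -1.27 ± 0.21 log2 units per doubling of age (SE, 6 mice). Fscn1, which bundles actin, fell from 603 CPM at 6 days to 58.8 CPM at 25 days (-1.67 ± 0.13), and Gpihbp1, which anchors lipoprotein lipase to capillaries, fell by 1.57 ± 0.14. Spock2 (2.02 ± 0.25) and the carbonic anhydrase gene Car4 (1.81 ± 0.25) rose. The chemokine gene Ccl21a, known from lymphatic vessels, was at 0 CPM at 6, 8 and 14 days and at 1149 CPM at 21 days (slope 11.32 ± 1.59), a call that was lost with the DESeq2 Wald test (adjusted p = 0.0574) and with predicted doublets kept (edgeR, adjusted p = 0.314). It has near-identical copies that can share reads. The proliferation list was called downward, 1 of 16 members falling (1 adjusted over the list alone, limma camera, adjusted p = 0.0372, and adjusted p = 0.430 with an estimated correlation). It was not called without the mouse of 6, 8 or 17 days (adjusted p = 0.263, 0.0701 and 0.107). In all, 315 genes rose and 294 fell of 6013 tested over 6 mice by edgeR (2028 called with all genes kept, 291 with a limit of 2 times). Leaving out the mouse of 6, 8, 21 or 25 days gave 290, 380, 311 and 281 genes, and counting the duplicated library at 3 days gave 9. Counting it at 11 days gave 810.

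In macrophage-like cells (cluster 11) the mixture of cells changed with age. Stfa1, a stefin gene of neutrophils, was at 13295 CPM at 6 days, 6631 CPM at 8 days and 0 CPM from 14 days on (slope -10.64 ± 1.00, SE, 6 mice), and Ngp, a granule protein gene, was at 782 and 3495 CPM and then 0. Cluster 11 was led by the neutrophil genes S100a8 and S100a9 beside macrophage genes such as C1qb, so it held more than macrophages. Leiden resolution 2 set the neutrophil genes apart in cluster 16, which stayed unnamed, with 34 cells at 6 days, 26 at 8 days, 0 at 14 and 17 days and 1 at 21 days. Macrophage-like cells were then 37 and 43 at 6 and 8 days, against 71 and 69 in cluster 11. Among them Stfa1 and Folr2 were still called by edgeR, and Ngp was no longer among the tested genes. Folr2, a folate receptor of resident macrophages, went from 57.6 CPM at 8 days to 768 CPM at 14 days (slope 2.68 ± 0.54). Of the tissue macrophage list 2 of 11 members rose (2 adjusted over the list alone, limma camera, adjusted p = 4.50e-05, and adjusted p = 0.247 with an estimated correlation). MHC class II genes, which present antigens, fell as a list with 2 of 7 members (4 adjusted over the list alone, limma camera, adjusted p = 0.00136, and adjusted p = 0.231 with an estimated correlation). At resolution 2 both lists were still called (limma camera, adjusted p = 0.000186 for tissue macrophage and 0.000182 for MHC class II). Proliferation genes were not called (limma camera, adjusted p = 0.758, 1 of 23 members rising, 1 adjusted over the list alone). Tdrd6, a gene of germ cells, was called as rising in this class (5.22 ± 0.94).

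Of 5649 genes tested over 6 mice by edgeR, 169 rose and 215 fell in macrophage-like cells (2082 called with all genes kept, 228 with a limit of 2 times). These calls rest on the 2 youngest mice: 5 genes were called without the mouse of 8 days and 29 without that of 6 days, against 246, 119 and 96 without those of 17, 21 and 25 days. By edgeR, Folr2 lost its call without the mouse of 6 days (adjusted p = 0.140) or 8 days (adjusted p = 0.123). Tdrd6 lost its call without the mouse of 6 or 8 days (edgeR, adjusted p = 0.0717 and 0.0971) and had a slope of 9.05 without that of 25 days. Ngp lost it without the mouse of 21 days (edgeR, adjusted p = 0.0511) and with the DESeq2 Wald test (adjusted p = 0.0561). Counting the duplicated library at 3 days left 1 gene and neither list (limma camera, adjusted p = 0.396 for tissue macrophage and 0.288 for MHC class II). Counting it at 11 days gave 451 genes.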

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

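Of the tests in this part only those of the Prm1 share at 25 days and of the stromal naming markers were chosen before their results had been seen; the tests of the duplicated library, of the share and number of spermatid UMIs, of doublets, of the gene minimum and of single libraries were chosen after. The duplicated library and the unnamed clusters of the next paragraph entered tests across ages and the Sertoli comparison only in alternatives.

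The library deposited at both 3 and 11 days held early-spermatocyte-like cells at 1.51% of its cells, above the limit that a count of 0 allows (0.0504%), against 0 of 9565 cells at 6 days and 0 of 5903 at 8 days. Sertoli-type cluster 8, with low UMIs and led by Defb36, Tsx and Cldn11, made up 8.36% of cells at 14 days and 10.0% at 17 days. Cluster 21, led by haemoglobin genes together with the Sertoli genes Rhox8 and Amh, made up 3.24% at 6 days and 13.1% at 8 days. Cluster 36, led by Tsx, Defb45, Rhox5 and Eppin together with the spermatid gene Smcp, made up 2.335% at 21 days, 2.34% at 25 days and 1.44% at 35 days. No explanation of these clusters was tested.

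The age of the duplicated library was weighed by the correlation of its class profiles, across genes, with those of 6, 8, 14 and 17 days. In 0 of 7 classes was the mouse of 6 days nearest, which argues against collection at 3 days. In 7 of 7 classes the nearest was that of 14 days, for macrophage-like cells with r = 0.935 against 0.740 at 6 days, which is consistent with 11 days. For vascular mural-like cells the margin was small (0.907 at 14 days, 0.905 at 6 days). The barcode suffixes of the tables rise with age, from 2 at 6 days and 3 at 8 days to 5 at 14 days and 9 at 35 days. That of the duplicated library is 4, between those of 8 and 14 days, which also argues against 3 days. Genes are not independent replicates, the series holds no other table of either age, and a mislabelled sample of another age near 14 days stays open.

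Spermatid transcripts were found in other cells from 21 days: Prm1 had a UMI in 64.7% of stromal-like cells at 21 days (median 7529 UMIs), in 100% at 25 days (median 7678) and in 62.3% at 35 days (median 6033), and in 0 at 14 and 17 days. Doublets with spermatids would be a minority, so 100% argues against them as the cause. At 25 days free RNA at a like share of every cell's UMIs was also argued against, since the share of the protamine and transition protein transcripts differed 3.51-fold between classes, over the bound of 3. After that came out, a further test was added. The mean number of their UMIs per cell differed 1.504-fold between the same classes, within its bound of 2, which is consistent with a like number of free UMIs in every droplet. Late-spermatocyte-like cells, with a median of 29770 UMIs, had the lowest share (0.146%). The share of Prm1 among these transcripts differed by 1.94 percentage points between classes, within the bound of 5 set beforehand, which is consistent with a single source. At 21 and 35 days the share of these transcripts differed 1.804-fold and 1.4406-fold between classes and their number per cell 1.428-fold and 1.847-fold. All of these lie within the bounds, so the 2 forms of free RNA cannot be told apart at those ages. The Prm1 share differed by 5.9 points at 21 days and 7.44 points at 35 days, between the bounds of 5 and 10, so a single source stays open there. The extremes rest on few UMIs, such as 146 in macrophage-like cells at 21 days and 65 in endothelial-like cells at 35 days. Classes left out of these comparisons were spermatids, unresolved late germ cells, T- or NK-like cells and unnamed cells, the last 2 at 25 days with these values: unnamed cells (share 0.785%, 40.5 UMIs per cell, Prm1 34.8%) and 3 T- or NK-like cells (Prm1 43.75%).

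Imprinted growth genes fell with age in stromal-like cells, 14 of 15 members. The call was lost with an estimated correlation (limma camera, adjusted p = 0.0655). With the preset correlation and at least 1800 genes in every library the adjusted p was 3.78e-08 by limma camera (8.36e-10 to 0.0655 over all alternatives), which argues against the gene minimum of the late tables. Dilution by RNA of other cells would lower the stromal naming markers alike. Their median slope was 0.0247, with Dcn at 0.79 ± 0.10 and Col3a1 at -0.48 ± 0.13. This cannot decide on dilution, because the fit left out genes of other classes and rescaled the libraries to the genes kept. The markers had also been used to name the clusters. Their slopes show only that they did not fall as a group as the imprinted genes did. A difference between single libraries cannot be told apart from age, because 0 ages have more than 1 mouse. A change with age stays open as the biological explanation and was not tested apart from that. Stromal-like cells lay in different clusters at different ages, and a change of cell population was not told apart from age either.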

How the results depend on the processing

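The settings chosen only after the data had been seen were the gene minimum of 1800, the top 5% of doublet scores, cluster 15 as stromal-like, the earlier naming rule, clusters 8 and 21 as Sertoli-like, clusters 8, 15, 21 and 36 as somatic, cluster 2 as early spermatocyte, cluster 18 as stromal-like, and the lists with the duplicated library at 3 or 11 days or at Leiden resolution 2. The naming rule itself was set after the clusters were seen and changed after its earlier version's names were seen. No paired analysis was possible between ages because each age has 1 mouse; only the X-linked share was compared within mice. For none of the changes below was anything beyond the setting examined: the cause was not tested, except that fewer mice or other genes enter by construction.

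The X-linked difference kept its direction in 10 of 10 alternatives, from -1.74 to -1.565 points with a mouse left out. Of 168 values of shares 119 stayed on the same side of the threshold, 31 were lost, 3 were gained and 15 reversed. For gene lists these were 180 of 214, with 19 lost, 8 gained and 7 reversed. Of 2700 values of named genes 2474 stayed and 226 were lost. A gene no longer tested in an alternative gave no value and was not counted as lost, such as Ngp at Leiden resolution 2. Of 96 counts of called genes 65 lay within 1.5 times the reported count, 26 lower and 5 higher.

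Correlations of shares with age are given as Pearson's r. With the duplicated library at 3 days the call was lost for stromal-like (-0.745), peritubular myoid-like (-0.783) and T- or NK-like cells (-0.593), and with age in days likewise (-0.869, -0.847 and -0.768). Against germ or somatic cells alone, r was 0.929 for stromal-like, 0.828 for endothelial-like, 0.844 for vascular mural-like and 0.675 for macrophage-like cells, each reversed, -0.0507 for T- or NK-like and -0.929 for spermatogonia-like cells. With clusters 8, 15, 21 and 36 added to the somatic cells it was 0.8757, 0.8573, 0.8259, 0.6717 and -0.1726 for the first 5 of these. With cluster 2 as early spermatocyte it was -0.96 for spermatogonia-like cells as a share of germ cells. With at least 1800 genes it was -0.841 for stromal-like, -0.767 for T- or NK-like and 0.00464 for macrophage-like cells, the last reversed. With cluster 18 as stromal-like it was -0.8059 for stromal-like, -0.7086 for peritubular myoid-like and -0.8572 for T- or NK-like cells, each lost. The earlier naming rule gave -0.362 for stromal-like, -0.473 for peritubular myoid-like and -0.857 for T- or NK-like cells. The share of T- or NK-like cells itself is unchanged in these 2 settings, where only the adjustment over the classes differs. T- or NK-like cells also lost the call with 1000 genes (-0.835) and without the top 5% of doublet scores (-0.808). Spermatogonia-like cells reversed at Leiden resolution 2 (0.0294). With a mouse left out, r ranged from -0.948 to -0.847 for stromal-like, -0.983 to -0.925 for peritubular myoid-like, -0.910 to -0.839 for T- or NK-like and -0.362 to 0.0167 for spermatogonia-like cells, the last without the mouse of 35 days.

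Counts of called genes in stromal-like, peritubular myoid-like, Leydig-like, endothelial-like and macrophage-like cells were 7547, 4134, 2830, 2028 and 2082 with all genes kept. By construction more genes of other cell types enter, and the share that rose went up: 4511 rising and 3036 falling, 2592 and 1542, 1992 and 838, 1546 and 482, 1545 and 537. With a limit of 2 times they were 1335, 1042, 649, 291 and 228. With the duplicated library at 3 days they were 1118, 1, 0, 9 and 1 by edgeR, against 3269, 1184, 1057, 1121 and 811 at an unadjusted p under 0.05. DESeq2 was not run with that library. At 11 days they were 3583, 2021, 1594, 810 and 451. The stricter cell filter gave 225 in macrophage-like cells, and the earlier naming rule 2148 in stromal-like cells. With a mouse left out they ranged from 2037 to 3282, 1342 to 1966, 440 to 1190, 281 to 639 and 5 to 447.

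For the gene lists, values are adjusted p by limma camera. An estimated correlation ended the call for fibrillar matrix in stromal-like cells (0.252), imprinted growth genes in stromal-like (0.0655) and peritubular myoid-like cells (0.0844), smooth muscle contraction (0.194), proliferation in peritubular myoid-like (0.0732), Leydig-like (0.0855) and endothelial-like cells (0.430), MHC class II (0.231) and tissue macrophage genes (0.247). The calls for adult Leydig genes (0.0480) and for imprinted growth genes in Leydig-like (0.0307) and endothelial-like cells (0.0460) held. With all genes kept, fetal Leydig (0.0193) and peritubular myoid fibrillar matrix genes (0.00713) were called, peritubular myoid proliferation was not (0.128), and stromal proliferation reversed (0.588). With the duplicated library at 3 days, proliferation was lost in peritubular myoid-like (0.354), Leydig-like (0.132) and endothelial-like cells (0.182) and reversed in macrophage-like cells (0.329). MHC class II (0.288) and tissue macrophage genes (0.396) were lost there, and peritubular myoid fibrillar matrix genes were called (0.0361).

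With a mouse left out, lists whose call changed ranged from 2.39e-06 to 0.548 for cholesterol biosynthesis (reversed without 25 days), 0.0417 to 0.995 for fetal Leydig (reversed without 6 or 8 days), and 0.00385 to 0.201 for peritubular myoid fibrillar matrix genes. For proliferation they ranged from 0.00018 to 0.0597 in Leydig-like, 0.000913 to 0.263 in endothelial-like and 0.232 to 0.979 in macrophage-like cells (reversed without 6 or 17 days). Over all alternatives, imprinted growth genes ranged from 8.36e-10 to 0.0655 in stromal-like, 3.23e-07 to 0.0844 in peritubular myoid-like, 2.21e-09 to 0.0307 in Leydig-like and 2.46e-06 to 0.0460 in endothelial-like cells. Adult Leydig genes ranged from 1.06e-06 to 0.0480, smooth muscle contraction from 3.78e-07 to 0.194, stromal fibrillar matrix genes from 1.14e-05 to 0.252, tissue macrophage genes from 2.71e-06 to 0.396 and MHC class II from 7.35e-05 to 0.288.

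Not run were all alternatives for trends in Sertoli-like cells and undifferentiated spermatogonia. The earlier naming rule in peritubular myoid-like cells and the gene minimum of 1800 in macrophage-like cells left 5 mice and gave no value. On simulated counts a slope of 0.5 was recovered for 1.01% of genes in macrophage-like and 36% in stromal-like cells. The share of such trends missed in the real counts cannot be read from these values. Fewer genes were changed in the simulation than were called in the real counts, and the Benjamini-Hochberg cutoff depends on the number of calls. What sets the recovery was not tested.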

Other observations

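The counts over other orders of the ages, the genes shared between classes and the free RNA of haemoglobin were chosen only after results had been seen.

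Genes were also compared across the 5 tested classes, and are named here after their values had been seen. Of 3610 genes tested in all 5, 8 rose in every class, among them Klf9, a glucocorticoid-induced transcription factor, Tns1, Brd2 and Calm3, against 0.00157 if the lists were independent. In every class 19 fell, among them the chromatin protein gene Ptma, the nuclear lamin gene Lmnb1, the kinase gene Akt1 and ribosomal protein genes such as Rpsa and Rps19, against 0.00356. The classes come from the same mice, so the excess was not separated from what those libraries share. With the duplicated library counted at 3 days 1 gene was called in peritubular myoid-like and 1 in macrophage-like cells, and at 11 days 2021 and 451.

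In cluster 1, a spermatogonial cluster present from 6 to 17 days, 38 of 40 proliferation genes were lower at 17 days (201 cells) than at 6 days (867 cells), with a median log2 ratio of -0.65 (percentile 0 among random lists). The microtubule regulator gene Stmn1 went from 1301 to 920.4 CPM. Of the perinatal germ cell list 7 of 10 members were higher (median 0.77, percentile 100), and the piRNA pathway gene Mov10l1 went from 87.3 to 174 CPM. At Leiden resolution 2, chosen for this after the values had been seen, these cells split into cluster 1 (394 cells at 6 days, 234 at 17 days) and an unnamed cluster 2 led in part by haemoglobin genes (479 and 7 cells), so the ages differ in mixture. Within that cluster 1, 38 of 40 proliferation genes were again lower (median -0.54, percentile 0), and 7 of 12 perinatal germ cell genes higher (median 0.51, percentile 99.9). These are 2 libraries, without a test. Haemoglobin transcripts made up 0.781% of UMIs in spermatogonia-like cells at 6 days and 0.00370% at 14 days.

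In the duplicated library, spermatogonia-like cells made up 35.4% of cells, stromal-like 26.4%, Sertoli-like 12.95%, peritubular myoid-like 11.7% and Leydig-like cells 5.07%. Its Sertoli-like cells had Cldn11 at 1509.9 CPM and Ube2c at 11.8 CPM. Meiotic chromosome genes summed to 1362 CPM and acrosome genes to 18.1 CPM.

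Chance was tested by fitting 80 orders of the ages, the real one included. As many genes as in the real order were called in 1 order for stromal-like (3316 genes, highest other 1686), 1 for peritubular myoid-like (1965, highest other 1569), 1 for Leydig-like (1359, highest other 824) and 1 for endothelial-like cells (609, highest other 549), the real order in each case. For macrophage-like cells 2 orders gave as many (384, highest other 412). Orders with as many genes were thus rare among the 80, and the lowest share these can give is 1 of 80. For macrophage-like cells another order called more genes than the real one. Exchanging the ages cannot part age from other differences between single libraries, because each age is 1 mouse. The highest other orders had rank correlations with age of -0.929, 0.943, 0.829, 0.943 and -0.714 in the same order of classes. The median of the other orders was 0 in each class.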
